A study of Arabidopsis thaliana with 18 samples.

How the data were processed

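RNA from 7-day seedling samples, as the labels describe them, was extracted with Trizol and made into TruSeq RNA libraries, per the labels' protocols. There were 18 libraries in 6 groups of genotype (wild type, bbx18 bbx23, pif4) and temperature (22 °C, 29 °C), with 3 replicates in each. The authors deposited a table of FPKM per gene, a unit named in the labels, with 1 column per library, and 0 columns were left without a sample. FPKM scales the reads of a gene by its length and by the number of reads in the library, and the deposited values are not whole numbers. Alignment was with Bowtie 0.12.2 to the build mm8, per the submitters' processing notes. Since mm8 is a mouse build and the table lists Arabidopsis loci, the genome, annotation and counter behind the values are not given in the sources used here. Which reads that number counts, and whether values were scaled further between libraries, is not given either. The summed FPKM differed between libraries, from 744698 to 1162160, and median-of-ratios size factors ran from 0.962 to 1.044. Organelle genes held 0.028% to 0.06% of the summed FPKM. Gene names and neighbouring genes were taken from the TAIR10.1 reference annotation, in which 32835 of the identifiers were found. That assembly was used for names, overlaps and sequence similarity only, not for the values.

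From the FPKM values, log2(FPKM + 1) was computed, and 19116 genes with at least 1 FPKM in at least 3 of the 18 libraries were kept. A linear model per gene, with a coefficient for each group, was fitted to all 18 libraries with limma 3.58.1 in R 4.3.3, using empirical Bayes variances with a trend on the mean. The 10 contrasts were tested, as 2-sided moderated tests with Benjamini-Hochberg adjustment within each contrast at 0.05: the warm response of each genotype, each mutant against the wild type at each temperature, the double mutant against pif4 at 29 °C, and the warm response of each mutant against that of the wild type. Gene lists were compared with camera at a preset correlation of 0.01 on the same model, adjusted over the 26 lists with at least 4 kept members, and again with an estimated correlation. The 28 lists, with 396 entries all found in the table, cover the targeted genes, hormone, growth, heat, light, clock, stress, metabolic and flowering genes, markers of roots, seed storage, senescence, cell division and handling, and reference genes. The targeted genes and the seed storage markers were described only. List members called are counted over all genes and adjusted over the list alone.

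The groups, contrasts, tests, filter, gene lists, most alternatives and the rule for naming genes were fixed before the data were examined. The rule names the 3 targeted genes, and, for the warm response in the wild type and each mutant against the wild type at 29 °C, up to 10 risen and 10 fallen genes of largest fold change. These must be called, have no overlap between the libraries of the groups, and reach a mean of 2 FPKM in the higher group. For the other contrasts it names up to 5 and 5, without the condition on overlap for differences of warm responses. From each list with a called member it adds up to 4 called members of smallest p, and any member of the auxin biosynthesis, PIF target and reference lists. It yielded 143 genes, and names were left out for length, never for their values. Close copies were searched with blastn 2.17.0, at 90% identity over 50% of the transcript or more.

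Alternatives were a pseudocount of 0.1, no filter on low values, size factors, only the libraries compared, no variance trend, each library left out in turn, and a block for replicate number. A block for replicate number within temperature, and leaving out replicate 1 or 2 at 29 °C in all genotypes, were added after replicates 1 and 2 at 29 °C were seen to deviate together by number. The pairing by number is not stated in the labels. It was checked by correlating deviations from the group means, and numbers were taken to pair libraries where every pair exceeded 0.1. This held for the wild type and the double mutant at 29 °C (0.70, 0.73 and 0.24) and for the wild type and pif4 at 22 °C (0.50, 0.49 and 0.60). The method was tested on simulated data with the observed spread: 67.2% of genes changed by 1 log2 were called in the wild-type warm response, 70.1% in pif4 against the wild type at 29 °C and 38.8% in the difference of warm responses, with 9, 6 and 3 false calls. For genes changed by 0.5 log2 these shares were 22.7%, 16.7% and 3%. Of 26 lists, the 1 that was shifted in simulation was called. Simulated noise was independent for every gene and library. It left out the deviations that libraries share by replicate number, and the correlation between genes of a list. The simulated shares and false calls therefore do not describe these libraries fully. For lists, they cannot show false calls that come from correlated genes. The sequenced reads were not used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with pandas 2.3.3.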

Results

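Gene expression was measured by RNA sequencing in Arabidopsis seedlings of the Columbia background, collected on day 7 and labelled 22 °C or 29 °C. Each temperature was sampled in the wild type, in a bbx18 bbx23 double mutant and in a pif4 mutant, with 3 libraries per group and 18 in total. BBX18 and BBX23 are B-box zinc finger proteins, a family known mostly from light signalling, and PIF4 is a basic helix-loop-helix factor known to drive hypocotyl elongation in the warm. The time spent at 29 °C is not given in the sources used here. Values are FPKM, and their sum per library ran from 744698 to 1162160. Summed FPKM averaged 1051330 ± 126860 (SD, n = 3) in the wild type at 22 °C and 856430 ± 93379 (SD, n = 3) at 29 °C. The 10 most abundant genes held 14% ± 1.2 (SD, n = 3) of the summed FPKM in the wild type at 22 °C and 8.4% ± 1.2 (SD, n = 3) at 29 °C. Read numbers are not part of the table. The smallest steps between its values imply about 24.8 to 31.4 M reads per library, an approximate figure that rests on reference exon lengths. Between 17791 and 18367 genes reached 1 FPKM in a library. Fold changes below are on the log2 scale of FPKM + 1, which understates the change of genes at low FPKM, and ± after the fold change of a gene gives its standard error, while ± after FPKM gives the SD. A gene is said to rise or fall where its limma adjusted p lay under 0.05. These p-values measure only the spread between these samples, and whether they are biological replicates is not given in the sources used here.

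The targeted genes were read first, in every group. BBX18 (AT2G21320) stood at 28.9 ± 1.37 FPKM (SD, n = 3) in the wild type at 22 °C and at 18.0 ± 2.57 (SD, n = 3) in the double mutant. That difference, -0.66 ± 0.71, had an adjusted p of 1, and at 29 °C it was -0.29 ± 0.71 with an adjusted p of 1. The SE of 0.71 is shared by all 6 groups and takes in the spread at 29 °C, where BBX18 ran from 9.43 to 64.4 FPKM in the wild type. The test therefore had little power for this gene at 22 °C. The libraries did not overlap at 22 °C, at 27.7 to 30.4 FPKM in the wild type and 16.4 to 20.9 in the double mutant. At 29 °C BBX18 was lower in the double mutant in 3 of 3 pairs of the same replicate number, and with a block for replicate number within temperature its SE was 0.14 and its adjusted p again 1. BBX23 (AT4G10240) was listed at 0 in all 18 libraries, so its value checks no label. PIF4 (AT2G43010) fell in the pif4 mutant at 29 °C, from 17.44 ± 1.72 to 9.32 ± 1.61 FPKM (SD, n = 3), a log2 fold change of -0.85 ± 0.13 with an adjusted p of 0.0109. This call was lost without replicate 1 of the wild type at 29 °C, or without replicate 1 or 3 of pif4 at 29 °C, with values from -0.96 to -0.74. At 22 °C PIF4 was at 10.1 ± 1.09 FPKM in the wild type and 7.05 ± 0.804 in pif4 (SD, n = 3). The double mutant therefore kept reads of BBX18 and pif4 those of PIF4, and a gene-level value cannot tell a disrupted transcript from an intact copy. PIF4 rose with temperature in the wild type by 0.74 (adjusted p = 0.00132).

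**Figure D1:**
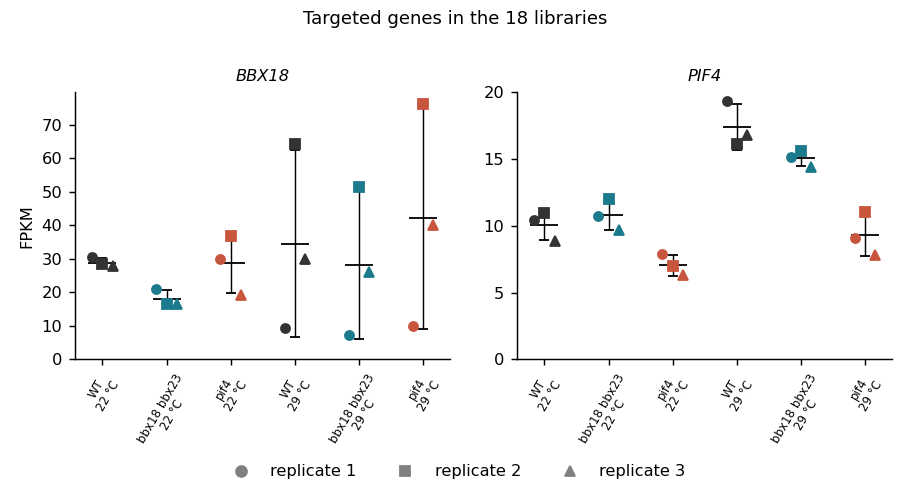
FPKM of BBX18 and PIF4 (vertical axes, linear from 0) in the 6 groups of genotype and temperature; symbols are the 3 replicates, horizontal bars the group means and whiskers 1 SD. PIF4 lies at 9.32 ± 1.61 FPKM in pif4 at 29 °C against 17.44 ± 1.72 in the wild type, while BBX18 at 29 °C spreads from 9.43 to 64.4 FPKM within the wild type alone.

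At 29 °C the libraries also varied by replicate number in all 3 genotypes. Temperature separated the libraries on the first principal component, with 41.9% of the variance, and the second, with 20%, separated replicates 1 and 2 at 29 °C. On the second, replicate 3 at 29 °C lay at -14.43 in the wild type, 0.52 in the double mutant and 20.1 in pif4. The wild type and pif4 at 29 °C were therefore not balanced along it. BBX18 at 29 °C was at 9.43, 64.4 and 29.9 FPKM in replicates 1, 2 and 3 of the wild type, at 7.12, 51.3 and 26.1 in the double mutant and at 10.1, 76.2 and 40.2 in pif4. The genes named in the rest of this paragraph were chosen after their values were seen. The morning clock gene PRR9 was at 0.041, 9.84 and 3.08 FPKM in replicates 1, 2 and 3 of the wild type at 29 °C, and the clock and cold gene COR27 at 26.3, 3.73 and 6.13. Replicate 2 exceeded replicate 1 at 29 °C by a mean of 4.35 log2 for the light-induced gene ELIP1, by 3.11 for SIG5 and by 3.51 for the chaperone gene HSP70. Over all tested genes, 580 differed by more than 1 log2 in the same direction in all 3 genotypes between these replicates at 29 °C, against 9 at 22 °C.

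**Figure D2:**
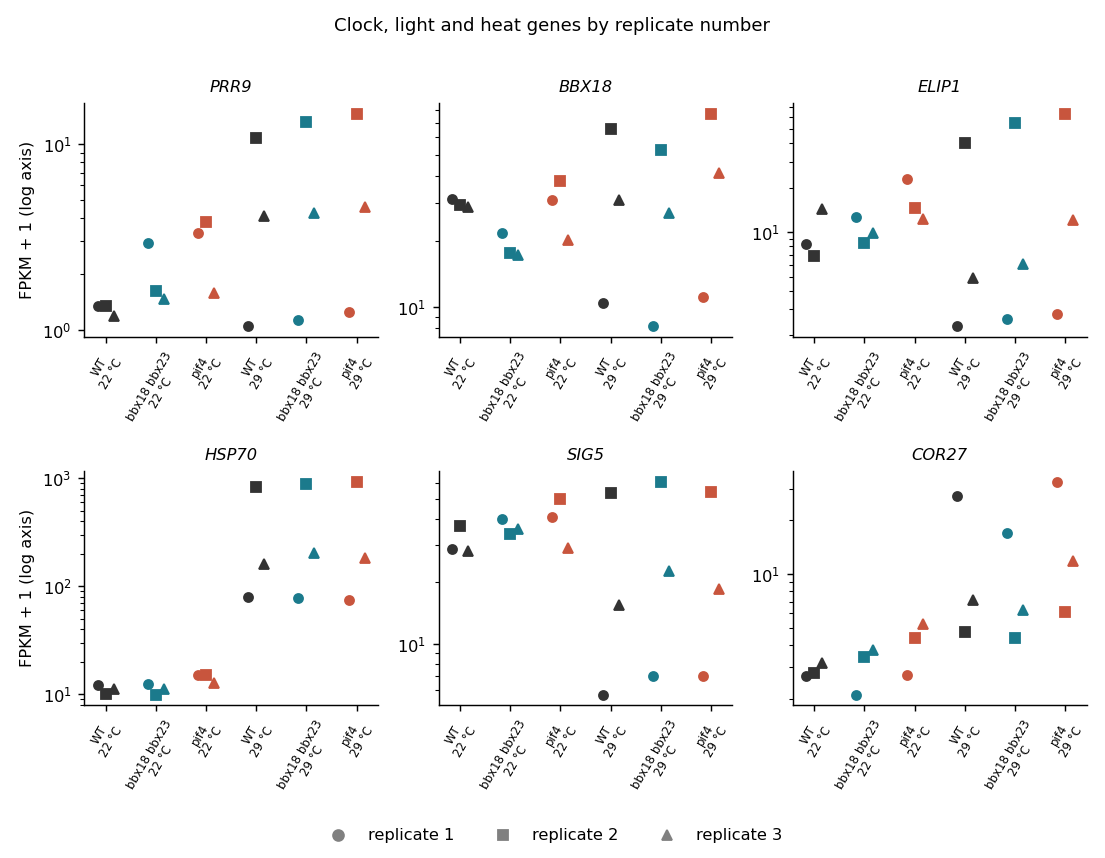
FPKM + 1 on log axes for PRR9, BBX18, ELIP1, HSP70, SIG5 and COR27 in the 6 groups; symbols mark replicates 1, 2 and 3. At 29 °C PRR9 reads 0.041, 9.84 and 3.08 FPKM in replicates 1, 2 and 3 of the wild type, and the order is alike in the mutants.

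Wild-type seedlings at 29 °C were compared with those at 22 °C to describe the warm response. The hour of harvest of each group is not given in the sources used here. A difference of hour or light between the groups at 22 °C and 29 °C could not be told apart from temperature. Among the genes that rose were those of several chaperones, and among those that fell were genes of light harvesting, anthocyanin synthesis and iron uptake. In limma, 1077 genes rose and 1634 fell, 305 and 348 of them by at least 2-fold, and 491 rose and 798 fell with only the libraries of these groups. HSP17.6A (AT5G12030) rose by 4.75 ± 0.71 (adjusted p = 2.83e-04), HSP17.4 (AT3G46230) by 4.66 ± 0.52 and HSP90.1 (AT5G52640) by 4.31, all known to keep proteins folded under heat. HSP23.6-MITO (AT4G25200), a mitochondrial member, went from 0.107 to 18.19 ± 6.56 FPKM (SD, n = 3). The heat shock factor gene HSFA3 (AT5G03720) rose by 1.89 ± 0.12 (adjusted p = 7.03e-08), and ST2A (AT5G07010), which encodes a sulfotransferase acting on hydroxyjasmonate, by 3.45 ± 0.29, from 3.04 ± 0.386 to 46.6 ± 23.9 FPKM (SD, n = 3). CYP82C4 (AT4G31940), known from the response to low iron, fell from 37.5 ± 2.19 to 0.841 ± 0.51 FPKM (SD, n = 3, adjusted p = 4.41e-08). The iron transporter gene IRT1 (AT4G19690) fell from 76.2 ± 14.6 to 6.84 ± 4.2 FPKM (SD, n = 3).

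The antenna protein gene LHCB1.1 (AT1G29920) fell from 13620 ± 2220 to 1337 ± 194 FPKM (SD, n = 3), LHCB2.3 (AT3G27690) from 1355 ± 214 to 121 ± 15.4, and CAO (AT1G44446), whose enzyme makes chlorophyll b, fell by 2.09. PORB (AT4G27440), which encodes a protochlorophyllide reductase, rose by 0.89. The anthocyanin enzyme gene DFR (AT5G42800) fell by 2.92 ± 0.15 and LDOX (AT4G22880) fell by 2.55. Among growth genes, the auxin response gene IAA19 (AT3G15540) rose from 8.94 ± 1.37 to 20.6 ± 0.846 FPKM (SD, n = 3), and the wall-loosening genes XTH17 (AT1G65310) and XTH24 (AT4G30270) rose by 1.85 and 2.04. The auxin synthesis gene YUC8 (AT4G28720) rose by 0.72 with an adjusted p of 0.0415. The YUC8 call was lost without any 1 of the wild-type libraries at 22 °C, or without replicate 1 or 3 at 29 °C, with values from 0.44 to 0.99. The evening clock genes LUX (AT3G46640), BOA (AT5G59570) and TOC1 (AT5G61380) rose by 2.48, 2.33 and 1.43, and the morning gene LHY (AT1G01060) fell by 1.35. Of the 82 named genes that rose or fell, 61 did so in all 6 fits that left out 1 library and 21 lost the call in at least 1. Reads of some of these genes cannot be assigned with certainty: LHCB1.1 has copies of at least 90% identity, XTH17 shares 90.7% with XTH18, and CYP82C4 has 2 close copies. HSP17.4, HSFA3, LHCB2.3, CAO, LUX and BOA overlap a gene on the opposite strand, and whether reads were counted by strand is not given in the sources used here.

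Of 26 fixed gene lists tested in the wild-type warm response, 10 shifted by camera with the preset correlation. Heat shock genes rose, 21 of 28 (25 adjusted over the list alone, median 2.54, adjusted p = 1.05e-18), with an adjusted p = 0.168 with an estimated correlation. Photosynthesis and chlorophyll genes fell, 27 of 28 (27 over the list alone, median -1.09, adjusted p = 2.91e-22, adjusted p = 0.0898 with an estimated correlation). Flavonoid and anthocyanin genes fell, 11 of 16 on either adjustment (median -1.19, adjusted p = 9.73e-11, adjusted p = 0.0898 with an estimated correlation). Aliphatic glucosinolate genes fell, 8 of 10 on either adjustment (median -0.88, adjusted p = 2.82e-09, adjusted p = 0.0898 with an estimated correlation), with the regulator MYB29 (AT5G07690) at -1.75. Circadian clock genes shifted upward, with 8 of 20 higher and 2 lower (11 and 4 over the list alone, median 0.94), and kept an adjusted p = 0.0212 with an estimated correlation beside 2.5e-04. PIF targets and PRE genes rose in 5 of 15 and fell in 1, on either adjustment (median 0.63, adjusted p = 0.00234, adjusted p = 0.256 with an estimated correlation). Cell wall expansion genes rose in 6 of 18 and fell in 1 (8 and 2 over the list alone, adjusted p = 0.00485, adjusted p = 0.393 with an estimated correlation).

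Handling and rapid stress genes, markers of disturbance at harvest, rose in 2 of 11 (3 over the list alone, median 0.62, adjusted p = 0.00312, adjusted p = 0.256 with an estimated correlation). Iron deficiency genes fell in 3 of 9 and FER1 (AT5G01600), which encodes the iron store ferritin, rose (4 and 1 over the list alone, adjusted p = 0.0104, adjusted p = 0.256 with an estimated correlation). Cell division genes fell in 4 of 8 (7 over the list alone, adjusted p = 9.63e-04, adjusted p = 0.168 with an estimated correlation). The other 16 lists did not pass the camera threshold. Auxin response genes had 4 of 17 higher (adjusted p = 0.11), auxin biosynthesis 1 higher and 2 lower of 11 (adjusted p = 0.42), SAUR growth genes 1 lower of 19 (adjusted p = 0.643) and brassinosteroid biosynthesis 1 lower of 7 (adjusted p = 0.94). The gibberellin list had 1 of 10 higher (2 over the list alone, adjusted p = 0.0688), the unfolded protein response list 2 of 9 lower (3 over the list alone, adjusted p = 0.0679), and the abscisic acid list 2 of 12 higher (adjusted p = 0.0688). B-box genes went both ways, 5 higher and 2 lower of 27 (adjusted p = 0.742): BBX22 (AT1G78600) rose by 1.48 and BBX3 (AT3G02380) fell by 2.16. Light signalling genes had 1 higher and 1 lower of 14 (1 and 2 over the list alone, adjusted p = 0.643), cold regulated genes 1 higher and 5 lower of 13 (2 and 7 over the list alone, adjusted p = 0.131), and flowering genes 1 higher and 2 lower of 5 (adjusted p = 0.864).

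Salicylic acid defence had 1 of 13 higher (0 over the list alone, adjusted p = 0.172), jasmonate 1 of 14 higher (adjusted p = 0.643) and senescence 1 of 4 lower (adjusted p = 0.94). Root markers had 0 of 7 in limma (adjusted p = 0.643, 4 higher and 3 lower by sign). Reference genes had 0 of 6 (adjusted p = 0.742), with PP2AA3 (AT1G13320) at 0.03 and UBQ10 (AT4G05320) at 0.26. Of 10 seed storage and oil body genes only OLEO4 (AT3G27660) passed the filter on low values, and it fell by 1.22. For the brassinosteroid, B-box, jasmonate, flowering and senescence lists the median, the mean and the camera test differ in sign. Several of these lists hold genes whose level follows the hour of the day, and the clock list moved with temperature as given above.

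**Figure D3:**
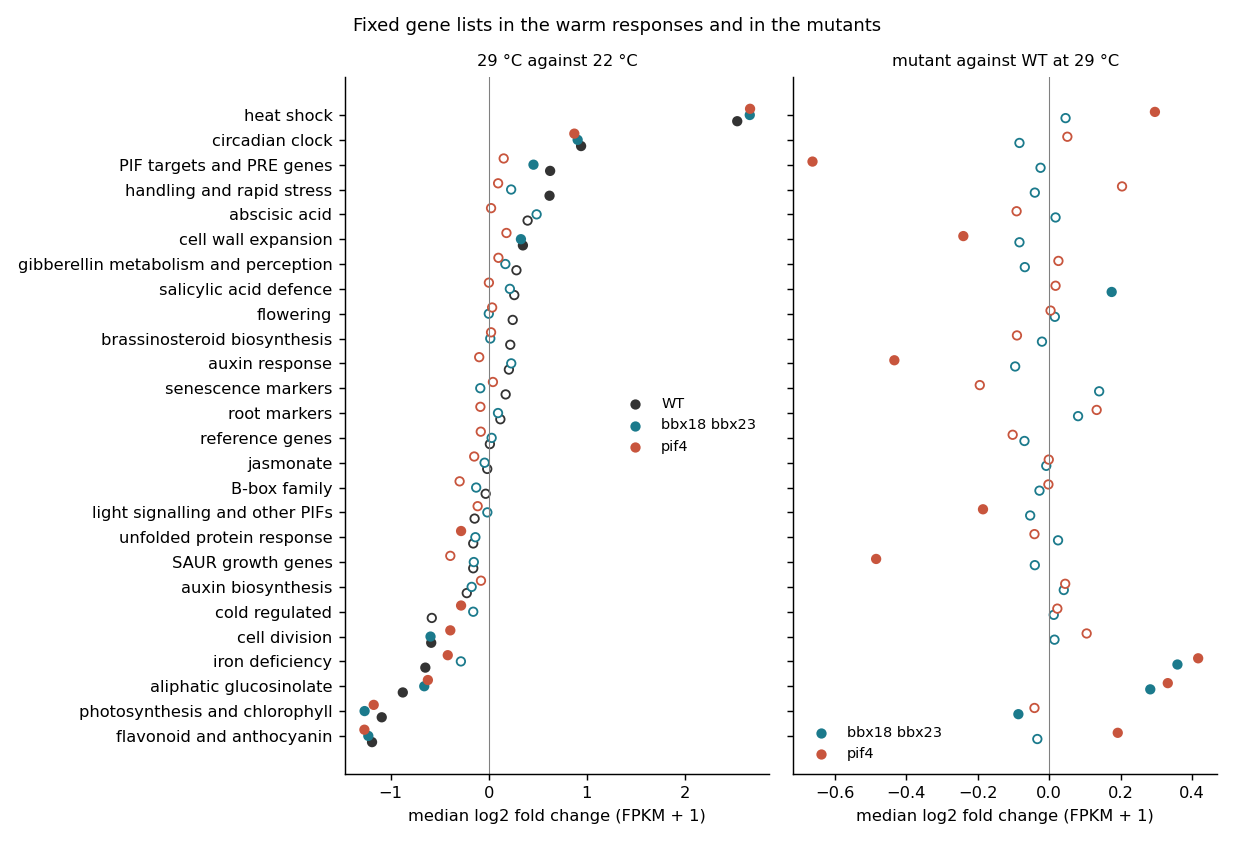
Median log2 fold change of FPKM + 1 (horizontal axes) over the members of each of the 26 tested gene lists, for 29 °C against 22 °C in the 3 genotypes (left) and for each mutant against the wild type at 29 °C (right); filled points passed camera at an adjusted p under 0.05 with the preset correlation, open points did not. Heat shock genes sit at 2.54 in the wild-type warm response, and PIF targets and PRE genes at -0.66 in pif4 against the wild type at 29 °C.

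The warm response was then measured in each mutant, to see which parts of it persisted. HSP17.4 rose by 4.55 in the double mutant and by 5.11 in pif4, CYP82C4 fell, with -4.05 and -4.44, and so did LHCB1.1, with -3.35 and -3.53. In the double mutant 1055 genes rose and 1541 fell, and in pif4 893 rose and 1622 fell, or 368 and 728 with only the pif4 libraries. The wild type and the double mutant shared 726 risen and 1225 fallen genes, where independent lists would share 59.4 and 131.7. The wild type and pif4 shared 628 and 1237, where independent lists would share 50.3 and 138.6. In all 3 genotypes 538 rose and 1086 fell, and 0 genes moved in opposite directions in limma between the wild type and either mutant, with 5123 wild-type genes at an unadjusted p under 0.05. Over the genes that rose in the wild type the median was 0.64 in the double mutant and 0.59 in pif4, and over those that fell it was -0.67 in each. With each replicate number held out of the selection, the risen genes had a median of 0.72 ± 0.24 (SD, n = 3) in the wild type, 0.69 ± 0.13 in the double mutant and 0.63 ± 0.06 in pif4. This SD is over 3 different selections, of 500 to 887 genes, and does not measure how genotypes differ on the same genes. Within a selection the medians, in the same order, were 0.89, 0.793 and 0.629 with replicate 1 held out, and 0.813, 0.737 and 0.685 with replicate 2. With replicate 3 held out the order reversed, at 0.448, 0.546 and 0.574. The fallen genes had -0.71 ± 0.04, -0.73 ± 0.02 and -0.72 ± 0.06 (SD, n = 3). Counts fell by over 1.5 times for the double mutant without its replicate 2 at 22 °C (1550) or its replicate 3 at 29 °C (1519), and for pif4 without its replicate 1 (1524) or 2 (1666) at 22 °C.

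In the double mutant, growth genes still rose at 29 °C: IAA19 by 0.93 (adjusted p = 7.79e-04), XTH17 by 1.62 and XTH24 by 1.41. Its warm response shifted 8 lists. Heat shock genes rose (21 of 28, 26 over the list alone, adjusted p = 1.03e-18, adjusted p = 0.152 with an estimated correlation). Lists that fell were photosynthesis (27 of 28 lower, adjusted p = 8.61e-26, adjusted p = 0.0844 with an estimated correlation), flavonoids (10 of 16 lower, 12 over the list alone, adjusted p = 5.86e-11, adjusted p = 0.0844 with an estimated correlation) and glucosinolates (6 of 10 lower, 8 over the list alone, adjusted p = 1.39e-05, adjusted p = 0.152 with an estimated correlation). The clock list (8 higher and 2 lower of 20, 10 and 4 over the list alone) had an adjusted p of 0.00193 and an adjusted p = 0.0622 with an estimated correlation. PIF targets (4 higher and 1 lower of 15) had 0.00358 and an adjusted p = 0.288 with an estimated correlation. Cell wall expansion (5 higher and 1 lower of 18, 7 and 3 over the list alone) had 0.0445 and an adjusted p = 0.653 with an estimated correlation, and was not called without replicate 2 at 29 °C in all genotypes (0.0658). Cell division (4 of 8 lower, 7 over the list alone) had 3.52e-04 and an adjusted p = 0.152 with an estimated correlation.

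In pif4, the wall-loosening expansin genes EXPA8 (AT2G40610) and EXPA1 (AT1G69530) fell at 29 °C, with -1.58 and -1.15, and the auxin response gene SAUR15 (AT4G38850) fell by 1.44, while XTH24 rose by 1.39. XTH17 was at 0.59 with an adjusted p of 0.0815. The warm response of pif4 shifted 9 lists. Heat shock genes rose (21 of 28, 24 over the list alone, adjusted p = 2.09e-22, adjusted p = 0.141 with an estimated correlation). Lists that fell were photosynthesis (26 of 28 lower, 27 over the list alone, adjusted p = 7.9e-23, adjusted p = 0.0839 with an estimated correlation), flavonoids (11 of 16 lower, 12 over the list alone, adjusted p = 7.9e-12, adjusted p = 0.0668 with an estimated correlation) and glucosinolates (6 of 10 lower, 8 over the list alone, adjusted p = 3.29e-05, adjusted p = 0.207 with an estimated correlation). The clock list (9 higher and 3 lower of 20, 11 and 3 over the list alone) kept its call, with an adjusted p = 0.0215 with an estimated correlation. So did the unfolded protein response list (4 of 9 lower on either adjustment, adjusted p = 0.00147, adjusted p = 0.0425 with an estimated correlation). Within it BIP2 (AT5G42020), 97.2% identical to BIP1, fell by 0.44. Cell division (2 of 8 lower, 7 over the list alone) had an adjusted p of 0.00579 and an adjusted p = 0.289 with an estimated correlation. Cold regulated genes (1 higher and 5 lower of 13, 1 and 6 over the list alone) had 0.0496 and an adjusted p = 0.676 with an estimated correlation, and were not called without replicate 1 at 29 °C in all genotypes (0.276). Iron deficiency genes (2 of 9 lower on either adjustment) had 0.0496 and an adjusted p = 0.573 with an estimated correlation. PIF targets and PRE genes did not pass in pif4 (1 of 15 lower, median 0.15, adjusted p = 0.756), nor did auxin response genes (adjusted p = 0.68).

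Whether a mutant responded to warmth differently was tested as the difference between its warm response and that of the wild type. For the double mutant, limma called 0 genes, with 133 at an unadjusted p under 0.05. The glucosinolate list differed by a median of 0.26 (adjusted p = 2.41e-07, adjusted p = 0.256 with an estimated correlation). Photosynthesis differed by -0.17 (adjusted p = 0.0355, adjusted p = 0.932 with an estimated correlation) and handling and rapid stress by -0.29 (adjusted p = 0.0221, adjusted p = 0.729 with an estimated correlation). The handling list already stood higher in the double mutant than in the wild type at 22 °C, as given below, and was not called between them at 29 °C. Without replicate 1 at 29 °C in all genotypes neither photosynthesis (0.998) nor handling (0.14) was called, and with size factors photosynthesis was not (0.0521). For pif4, 3 genes responded less than in the wild type: ST2A with a difference of -2.70 ± 0.41 (adjusted p = 0.0422), AT5G02540, which encodes a Rossmann-fold oxidoreductase, with -2.27 ± 0.33 (adjusted p = 0.0409), and AT5G44440, a berberine bridge enzyme-like gene, with an adjusted p of 0.0398. AT5G44440 went from 0.108 ± 0.0982 to 3.18 ± 0.975 FPKM (SD, n = 3) in the wild type and was listed at 0 in pif4 at 29 °C. The count of 3 became 0 without replicate 1, 2 or 3 of the wild type at 22 °C, replicate 3 of the wild type at 29 °C, replicate 1 or 3 of pif4 at 22 °C, or replicate 1 or 2 of pif4 at 29 °C. It became 1 without replicate 1 of the wild type at 29 °C, and 6 without replicate 3 of pif4 at 29 °C. A pseudocount of 0.1 gave 0 genes, no filter on low values 1, a block for replicate number 5, and that block within temperature 8.

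Growth lists responded less in pif4 than in the wild type with the preset correlation. The medians of the difference were -0.48 for PIF targets and PRE genes (adjusted p = 3.78e-08, adjusted p = 0.0687 with an estimated correlation), -0.37 for cell wall expansion (3.88e-07, adjusted p = 0.153 with an estimated correlation), -0.28 for auxin response (2.64e-06, adjusted p = 0.0687 with an estimated correlation) and -0.29 for SAUR genes (0.00753, adjusted p = 0.52 with an estimated correlation). Lower too were handling and rapid stress at -0.37 (0.00114, adjusted p = 0.288 with an estimated correlation), abscisic acid at -0.27 (0.0367, adjusted p = 0.659 with an estimated correlation), salicylic acid defence at -0.20 (0.0367, adjusted p = 0.52 with an estimated correlation) and the unfolded protein response at -0.14 (0.0125, adjusted p = 0.0966 with an estimated correlation). Glucosinolate genes differed by 0.29 (6.77e-08, adjusted p = 0.1 with an estimated correlation). Without replicate 1 at 29 °C in all genotypes, SAUR genes (0.415), salicylic acid defence (0.472) and abscisic acid (0.0722) were not called. No list test left out replicate 3 at 29 °C, where the wild type and pif4 were not balanced on the second principal component. Of the PIF target list, IAA19, IAA29, YUC8 and XTH15 also stand in the auxin or cell wall lists.

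The double mutant was compared with the wild type at each temperature to find genes that depend on BBX18 and BBX23. At 22 °C 5 genes rose and 0 fell in limma, with 249 at an unadjusted p under 0.05, and 1 rose with only the libraries compared. AT2G41640, which encodes a family 61 glycosyltransferase, rose from 5.56 ± 1.09 to 19.7 ± 1.7 FPKM (SD, n = 3, adjusted p = 1.76e-05). ARP9 (AT5G43500), an actin-related gene, rose from 3.096 ± 0.191 to 8.17 ± 1.18 FPKM (SD, n = 3, adjusted p = 0.00907), AT1G42430 from 40.6 ± 2.45 to 75.1 ± 7.13, the noncoding AT4G04223 from 6.35 ± 2.07 to 31.7 ± 9.39, and AT3G56210 from 16.1 ± 3.48 to 38.9 ± 8.05. The count was 1 without replicate 2 and 2 without replicate 3 of the wild type at 22 °C, and 3, 1 and 2 without replicates 1, 2 and 3 of the double mutant at 22 °C. AT2G41640 overlaps AT2G41650 on the same strand, and AT4G04223 matches AT3G56210 at 99.5% identity, so their reads may not be separable. Handling and rapid stress genes (median 0.29), salicylic acid defence (0.12) and flavonoids (-0.10) shifted with an adjusted p of 0.0276 each, 0 members called by limma, and an adjusted p = 0.714, 0.714 and 0.965 with an estimated correlation.

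At 29 °C 3 genes rose in the double mutant and 0 fell in limma, with 211 at an unadjusted p under 0.05, and 0 were called with only the libraries compared. These 211 are fewer than a share of 0.05 of the 19116 tested genes, as in every contrast between genotypes. Mutant and wild-type libraries did not overlap for 4.4% of genes, where random groups would give 10%. The fit without a block counts deviations shared by replicate number as spread, so few calls do not show an absence of effect. AT2G41640 rose from 7.95 ± 0.785 to 19.6 ± 0.862 FPKM (SD, n = 3, adjusted p = 0.00173), ARP9 from 2.63 ± 0.64 to 7.49 ± 0.504, and AT4G04223 from 7.41 ± 2.63 to 33.6 ± 6.39. AT4G04223 lost its call without replicate 3 of the wild type, or replicate 1 or 3 of the double mutant, at 29 °C. Without replicate 1, or without replicate 2, at 29 °C in all genotypes, 0 genes were called by limma. PIF-dependent growth genes did not pass here: IAA19 was at -0.36 ± 0.16, XTH15 (AT4G14130) at -0.52 ± 0.25, PIF4 at -0.20 and YUC8 at -0.18, each with an adjusted p of 1. Each of these 4 was lower in the double mutant in 3 of 3 pairs of the same replicate number, as were 1861 of the 19116 tested genes and 4 of the 15 PIF targets and PRE genes. With a block for replicate number within temperature the SE was 0.12 for IAA19 and 0.19 for XTH15, and the adjusted p stayed at 1 for all 4. PIF targets and PRE genes had an adjusted p of 0.418 and auxin response genes 0.179. The glucosinolate list stood higher, by a median of 0.28 with 10 of 10 members higher by sign (0 called over all genes, 1 over the list alone, adjusted p = 2.99e-09, adjusted p = 0.232 with an estimated correlation). Iron deficiency genes stood higher by 0.36 and salicylic acid defence by 0.18, and photosynthesis lower at -0.09, each with an adjusted p of 0.0431 and an adjusted p = 0.892 with an estimated correlation. With a block for replicate number within temperature, photosynthesis and salicylic acid defence both had an adjusted p of 0.117 and were not called. Without replicate 1 at 29 °C photosynthesis (0.689, reversed) and iron deficiency (0.243) were not called, nor was salicylic acid defence without replicate 2 (0.0939).

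The pif4 mutant was compared with the wild type at 22 °C to see which genes differ at the lower temperature. In limma 4 genes rose and 0 fell, with 619 at an unadjusted p under 0.05. The noncoding AT2G01422 rose from 0.0803 ± 0.139 to 15.4 ± 2.92 FPKM (SD, n = 3, adjusted p = 7.19e-09) and the noncoding AT2G05914, which overlaps AT2G05915 on the opposite strand, from 0.4 ± 0.253 to 3.54 ± 0.476. AT4G04223 rose to 59.2 ± 14.3 FPKM and AT3G56210 to 41.9 ± 8.72 (SD, n = 3). AT3G56210 lost its call without replicate 1 or 2 of the wild type, or replicate 1 or 3 of pif4, at 22 °C, with values from 1.15 to 1.48. With a block for replicate number within temperature, 13 genes were called, 11 higher and 2 lower.

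At 22 °C 8 lists shifted in pif4 with 0 members called over all genes. SAUR growth genes (median -0.34, adjusted p = 0.00122, adjusted p = 0.4 with an estimated correlation), auxin response genes (-0.17, 0.0104, adjusted p = 0.353 with an estimated correlation) and light signalling genes (-0.12, 0.0283, adjusted p = 0.353 with an estimated correlation) stood lower. Handling and rapid stress genes stood higher by 0.61, with 2 of 11 higher over the list alone (adjusted p = 1.24e-06, adjusted p = 0.297 with an estimated correlation). So did root markers, by 0.39 with 7 of 7 higher by sign (adjusted p = 0.00236, adjusted p = 0.4 with an estimated correlation). Cold regulated genes (0.33, 0.00568, adjusted p = 0.4 with an estimated correlation), flavonoids (0.27, 0.00568, adjusted p = 0.4 with an estimated correlation) and salicylic acid defence (0.20, 0.0262, adjusted p = 0.4 with an estimated correlation) stood higher alongside these markers. With the block within temperature salicylic acid defence had an adjusted p of 0.0565, and PIF targets (0.0144), heat shock (0.0434) and iron deficiency (0.0443) passed.

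At 29 °C the pif4 mutant was compared with the wild type to find the genes that need PIF4 in the warm. The auxin response gene IAA19 was among those that fell. In limma 19 genes fell and 7 rose, with 630 at an unadjusted p under 0.05, and with only the libraries compared 3 fell and 3 rose. IAA19 fell from 20.6 ± 0.846 to 6.03 ± 1.31 FPKM (SD, n = 3, adjusted p = 4.84e-05). AT5G02540 fell from 114 ± 19.8 to 14.7 ± 4.42 (adjusted p = 1.37e-05), ST2A from 46.6 ± 23.9 to 6.74 ± 1.2, and FAR1 (AT5G22500), which encodes a fatty acyl reductase, from 38.6 ± 10.8 to 7.31 ± 2.28. COR413IM1 (AT1G29395) fell from 50.5 ± 5.18 to 12.9 ± 1.44, the desaturase gene ADS1 (AT1G06080) from 48.2 ± 3.58 to 13.8 ± 5.29, AT2G47780 from 12.4 ± 1.13 to 1.84 ± 1.15, and FLP1 (AT4G31380), a flowering-promoting factor gene, from 11.3 ± 1.44 to 3.18 ± 1.33. AT5G44440 went from 3.18 ± 0.975 FPKM to a listed 0 (adjusted p = 4.84e-05). Of the 19 fallen genes, 14 rose with temperature in the wild type, beside 1077 of all 19116 tested genes. Both contrasts use the same wild-type libraries at 29 °C, and in 100 simulations of unchanged mutants the 19 genes with the lowest t in pif4 held a mean of 7.5 such genes, with a highest of 14. Those simulated genes are picked on noise alone, unlike genes called in pif4, so they are no close measure for these 19. FAR1 and AT2G47780 overlap a gene on the opposite strand.

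Further genes fell in pif4 at 29 °C by calls that rest on single libraries. IAA7 (AT3G23050), an auxin repressor gene, fell from 216 ± 15.2 to 137 ± 14.3 FPKM (SD, n = 3, adjusted p = 0.0139) and lost its call without replicate 2 or 3 of the wild type or 1 or 2 of pif4, with values from -0.74 to -0.61. IAA34 (AT1G15050) fell by 1.56 (adjusted p = 0.0122), lost without replicate 3 of the wild type or 2 of pif4, and overlaps AT1G15060 on the same strand. XTH17 fell by 1.14 (adjusted p = 0.0498), lost without any 1 of the wild-type libraries or replicate 1 or 2 of pif4, with values from -1.46 to -0.86. XTH15 was at -1.26 (adjusted p = 0.0871) and YUC8 at -0.78 (adjusted p = 0.703). HFR1 (AT1G02340) and IAA29 (AT4G32280) were at -1.23 and -1.26 with an adjusted p of 1. AT2G01422 rose by 3.77 (adjusted p = 1.3e-08), AT4G04223 by 2.87 and AT2G05914 by 1.81. The rises of UBC12 (AT3G08700), 1.56, GSTF11 (AT3G03190), 0.92, and AT3G56210, 1.31, each lost their call without replicate 1 of the wild type at 29 °C. UBC12 lost it also without replicate 1 or 2 of pif4, and GSTF11 also without replicate 2 or 3 of the wild type or of pif4. XTH15 overlaps a gene on the opposite strand. So does GSTF11, with NAC045 (AT3G03200), which it matches at 100% identity over 94.9% of its exons. Without replicate 1 of the wild type, or without replicate 2 of pif4, 15 genes were called in place of 26, and without replicate 1 or 2 at 29 °C in all genotypes 14 and 13.

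PIF targets and PRE genes stood lower in pif4 at 29 °C, with a median of -0.66, with 14 of 15 lower by sign, 1 called over all genes and 5 over the list alone (adjusted p = 1.01e-14, adjusted p = 0.00828 with an estimated correlation). Auxin response genes stood lower, with a median of -0.43, with 16 of 17 lower by sign, 2 called and 4 over the list alone (adjusted p = 4.17e-13, adjusted p = 0.00464 with an estimated correlation). SAUR growth genes stood lower, with -0.48 (0 called, 1 over the list alone, adjusted p = 1.86e-11, adjusted p = 0.0552 with an estimated correlation). So did cell wall expansion with -0.24 (1 called, 3 over the list alone, adjusted p = 3.04e-05, adjusted p = 0.274 with an estimated correlation) and light signalling with -0.19 (0 called, 1 over the list alone, adjusted p = 0.012, adjusted p = 0.134 with an estimated correlation). Glucosinolate genes stood higher by 0.33 (0 called, 3 over the list alone, adjusted p = 5.17e-10, adjusted p = 0.0552 with an estimated correlation). Iron deficiency (0.42, adjusted p = 0.0252, adjusted p = 0.477 with an estimated correlation), heat shock (0.30, adjusted p = 0.0368, adjusted p = 0.7 with an estimated correlation) and flavonoid genes (0.19, adjusted p = 0.0368, adjusted p = 0.661 with an estimated correlation) stood higher with 0 members called by limma. Without replicate 1 at 29 °C in all genotypes, cell wall expansion (adjusted p = 0.161), heat shock (0.588) and iron deficiency (0.0913) were not called, nor was heat shock without replicate 2 (0.348). No list test left out replicate 3 at 29 °C, which lay at -14.43 in the wild type and 20.1 in pif4 on the second principal component. How far this imbalance moved the lists was not tested.

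**Figure D4:**
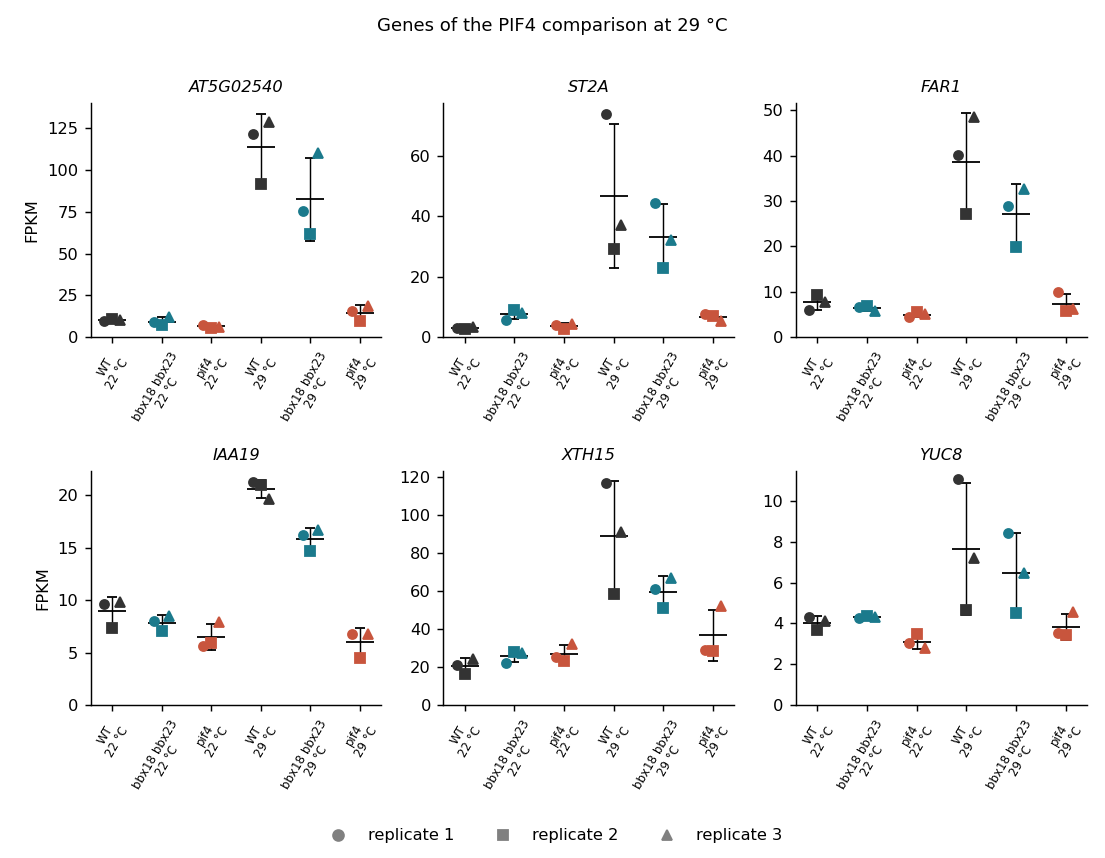
FPKM (vertical axes, linear from 0) of AT5G02540, ST2A, FAR1, IAA19, XTH15 and YUC8 in the 6 groups of genotype and temperature; symbols are the 3 replicates, horizontal bars the group means and whiskers 1 SD. At 29 °C IAA19 lies at 20.6 ± 0.846 FPKM in the wild type, 15.9 ± 1.05 in bbx18 bbx23 and 6.03 ± 1.31 in pif4. ST2A, FAR1, XTH15 and YUC8 spread widely between replicates, with ST2A at 46.6 ± 23.9 FPKM in the wild type at 29 °C.

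The mutants were compared with each other at 29 °C to see where they differ. This contrast holds no wild-type library, so it cannot show whether BBX18 and BBX23 act on the genes that need PIF4. A gene lowered only in part in the double mutant would also stand higher there than in pif4. IAA19 was higher in the double mutant than in pif4, at 15.9 ± 1.05 against 6.03 ± 1.31 FPKM (SD, n = 3, adjusted p = 0.00142). AT5G02540 was higher by 2.41 (adjusted p = 1.27e-04), ST2A by 2.104 (adjusted p = 0.00388) and FAR1 by 1.77 (adjusted p = 0.00207), and AT5G44440 was at 2.71 ± 1.06 FPKM (SD, n = 3) against a listed 0. In limma 13 genes were higher and 5 lower, and with only the libraries compared 0 were higher and 1 lower. AT2G01422 and AT2G05914 were lower, with -3.71 and -1.75, as were AT5G35935, a pseudogene, with -0.99, and AT4G16146 with -1.31, a call lost without replicate 2 of pif4. PIF targets and PRE genes stood higher in the double mutant by a median of 0.60 (1 called, 7 over the list alone, adjusted p = 3.04e-19, adjusted p = 0.0027 with an estimated correlation), auxin response genes by 0.38 (1 called, 2 over the list alone, adjusted p = 6.16e-15, adjusted p = 0.0027 with an estimated correlation) and SAUR genes by 0.53 (0 called, 1 over the list alone, adjusted p = 3.66e-16, adjusted p = 0.0222 with an estimated correlation).

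With the preset correlation alone, cell wall expansion (0.18, adjusted p = 3.22e-04, adjusted p = 0.335 with an estimated correlation), salicylic acid defence (0.12, adjusted p = 0.0168, adjusted p = 0.356 with an estimated correlation) and light signalling genes (0.12, adjusted p = 0.0478, adjusted p = 0.334 with an estimated correlation) stood higher in the double mutant than in pif4. Flavonoids (-0.17, adjusted p = 3.42e-06, adjusted p = 0.29 with an estimated correlation), heat shock (-0.15, adjusted p = 0.00259, adjusted p = 0.658 with an estimated correlation) and handling and rapid stress genes (-0.19, adjusted p = 0.0168, adjusted p = 0.356 with an estimated correlation) stood lower. Without replicate 1 at 29 °C in both mutants and the wild type, cell wall expansion (0.232), heat shock (0.584) and handling (0.884) were not called, and 10 genes were called in place of 18, against 7 without replicate 2. No list test left out replicate 3 at 29 °C, which lay at 0.52 in the double mutant and 20.1 in pif4 on the second principal component. Against the wild type at 29 °C, 18 of the 19 genes that fell in pif4 were also lower by sign in the double mutant, with a median of -0.34 against -1.56 in pif4 and 0 called in the double mutant. Of the 19, 16 were lower in all 3 pairs of the same replicate number. In 100 simulations of unchanged mutants against shared controls, the 19 genes with the lowest t in pif4 gave means of 18.1 lower by sign and 12.7 lower in all 3 pairs, with highest values of 19 and 17. These genes were selected on pif4, and both contrasts use the same 3 wild-type libraries, which could not be halved. No gene was changed in the simulations, so their 19 genes are picked on the noise of the wild-type and pif4 libraries alone. The real 19 were called in pif4, so the simulated numbers cannot decide whether their lower values in the double mutant come from the shared controls. AT4G04223 rose in both mutants, where independent lists would share 0.0011 genes and 100 simulations of unchanged mutants against shared controls 0. That overlap became 0 without replicate 3 of the wild type or replicate 1 or 3 of the double mutant at 29 °C. Across genes, which are not independent replicates, the fold changes of the mutants had r = 0.58 and rho = 0.603, where shared controls alone gave 0.499 and 0.467 in simulation. The covariance was 0.0194 beside a simulated 0.028, below the lowest simulated value of 0.026. These simulations draw every library independently and leave out the deviation that libraries of the same replicate number share at 29 °C, so they do not describe these libraries fully. Part of the excess of the correlation over 0 may come from the shared controls.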

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

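The tests of roots as the whole of the replicate pattern, on the genes higher in both mutants and on BBX18 in the double mutant, the block for replicate number within temperature, and leaving out whole replicate numbers at 29 °C were chosen only after the result was seen. Differences between the warm responses of genotypes, by a test of the difference itself, drew attention to 15 results, given first as values. In the double mutant against the wild type, the median difference was -0.166 for photosynthesis and chlorophyll, 0.263 for aliphatic glucosinolates and -0.292 for handling and rapid stress (adjusted p = 0.0355, 2.41e-07 and 0.0221). In pif4 against the wild type, AT5G02540 differed by -2.268, AT5G44440 by a fitted -1.905, which is no bound since it is listed at 0 in pif4 at 29 °C, and ST2A by -2.70 (adjusted p = 0.0409, 0.0398 and 0.0422). The count of these 3 genes moved to 0 without replicate 1, 2 or 3 of the wild type at 22 °C, replicate 3 of the wild type at 29 °C, replicate 1 or 3 of pif4 at 22 °C, or replicate 1 or 2 of pif4 at 29 °C, to 1 without replicate 1 of the wild type at 29 °C and to 6 without replicate 3 of pif4 at 29 °C. List medians in the same contrast were -0.277 for auxin response, -0.285 for SAUR growth genes, -0.368 for cell wall expansion, -0.482 for PIF targets and PRE genes, -0.14 for the unfolded protein response, -0.199 for salicylic acid defence, -0.273 for abscisic acid, 0.293 for aliphatic glucosinolates and -0.369 for handling and rapid stress. Of these 12 list differences, 0 passed camera with an estimated correlation.

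The first pattern weighed is that libraries of replicates 1 and 2 at 29 °C deviate together by number in all 3 genotypes. Those of replicate 3 did so less or not at all. Their deviations correlated at 0.24 between the wild type and the double mutant, -0.32 between the wild type and pif4, and 0.05 between the mutants. Different sequencing depth is argued against, since 128 genes of at least 50 FPKM differed by over 1 log2 in the same direction in all genotypes, 67 higher and 61 lower in replicate 2. Harvest at different times around lights-on, or different light exposure, is a candidate explanation: 11 acute light response genes were higher in replicate 2 than in replicate 1 by a median of 1.63 log2, at 1.68, 1.59 and 1.63 in the wild type, the double mutant and pif4. Among them ELIP1 (4.35) and SIG5 (3.11) were named above after their values were seen, so these add no independent support. The other members ran from 0.88 for SPA4 to 2.74 for ELIP2. A different share of roots as the whole of the pattern is argued against, since 62 of the 67 higher genes exceeded the largest root marker difference in all 3 genotypes, and in the double mutant root markers lay between -0.23 and 0.27. A different share of roots as a smaller part stays open, with a median of 0.41 over 7 root markers and 0.62, 0.01 and 0.6 in the genotypes. The design names no biological difference between replicates, so none was tested.

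The second pattern is that AT4G04223 and AT3G56210 are higher in both mutants than in the wild type at both temperatures. A chance deviation of the shared wild-type libraries was weighed with the genes called higher in both mutants at 22 °C, chosen there alone. Of these, 2 of 2 lay above every wild-type library in both mutants at 29 °C, as did 0.81% of all tested genes. The wild-type libraries at 29 °C are others, which argues against a chance deviation of those at 22 °C. The pattern was named from both temperatures before this test was written, so its outcome was known. With a match of 99.5%, the 2 genes may be 1 signal. AT3G56210 was called in 3 of the 4 contrasts with the wild type, and its call in the double mutant at 22 °C was lost without any 1 of the 6 libraries. A difference of the wild-type seed line outside the named genes may remain: 0 of these genes were called between the mutants at 29 °C in limma, where 318 genes had an unadjusted p under 0.05. AT4G04223 was lower in the double mutant than in pif4 at 29 °C, with -0.788 ± 0.286 (33.6 ± 6.39 against 58.6 ± 10.3 FPKM, SD, n = 3, adjusted p = 1), and at 22 °C it averaged 31.7 against 59.2 FPKM. AT3G56210 differed less, with -0.236 ± 0.192 at 29 °C (adjusted p = 1). As neither gene was called between the mutants, these values leave a difference of the seed line open. Reads shared by the 2 genes stay open too, as their sequences match at 99.5%, so the 2 are not independent, and they deviate in the same direction in 11 of 18 libraries. An effect of each mutation on these genes was not told apart from those by any test.

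The third pattern is that the BBX18 transcript was still measured in the double mutant. Libraries made of seedlings of the same wild-type line are argued against, since 3 genes, AT2G41640, AT4G04223 and ARP9, were called in the same direction at both temperatures with no overlap of mutant and wild-type libraries. Wild-type seedlings of another seed line are not told apart by these calls, and AT4G04223 also rose in pif4. Of the 3, AT2G41640 kept both calls with any 1 library left out, while ARP9 lost its call at 22 °C in 4 of 6 such fits and AT4G04223 lost its call in 3 of 6 at each temperature. Without replicate 1, or without replicate 2, at 29 °C in all genotypes 0 of the 3 were called at 29 °C. An insertion that leaves part of the transcript may account for it and stays open, as the table gives 1 FPKM per gene and 0 values along it.

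Other splits of the same libraries were counted for each contrast. With 10 splits of 6 libraries no share under 0.05 can be reached. The real split called 2711, 2596 and 2515 genes in the warm responses of the wild type, the double mutant and pif4, and the highest of the others 0. It called 5 and 3 genes in the double mutant against the wild type at 22 °C and 29 °C, where the highest other was 0, and 4 in pif4 at 22 °C, where it was 1. For each of these contrasts 1 of the 10 splits, the real one, called as many. For pif4 against the wild type at 29 °C 2 of 10 splits called at least the real 26, the highest other 1799, and for the double mutant against pif4 2 of 10 called at least the real 18, the highest other 512. Each of these high counts came from the split that set replicates 1 and 3 of the wild type or the double mutant and replicate 1 of pif4 against the other 3 libraries, so it follows a difference between libraries other than genotype. For the differences of warm responses 100 splits were drawn: 12 called at least the real 3 for pif4 (highest other 1140), a share that does not exclude chance. Of the 11 others that did so, 8 kept the real groups at 29 °C and regrouped only 22 °C, so they carry the real difference at 29 °C and are no measure of chance. The remaining 3 set replicates 1 and 3 of the wild type and replicate 1 of pif4 at 29 °C against the rest, out of 88 that regrouped 29 °C. For the double mutant all 100 called at least the real 0 (highest other 7), which any split does, so the count tests nothing there.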

How the results depend on the processing

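The block for replicate number within temperature and the fits without the libraries of replicate 1 or 2 at 29 °C were chosen after seeing the data. With an estimated correlation the lists called went from 10 to 1 (wild-type warm response), 8 to 0 (double mutant), 9 to 2 (pif4), 3 to 0 and 4 to 0 (double mutant against wild type at 22 °C and 29 °C), 8 to 0 and 9 to 2 (pif4 likewise), 3 to 0 and 9 to 0 (differences of warm responses, double mutant and pif4) and 9 to 3 (double mutant against pif4). With only the compared libraries, which leaves fewer samples for the spread, genes called were 1289 (wild-type warm response), 1096 (pif4), 1 and 0 (double mutant at 22 °C and 29 °C), 6 (pif4 at 29 °C, 3 higher and 3 lower) and 1 (double mutant against pif4). In the following settings the cause was not tested. No filter gave 7 genes for pif4 at 22 °C, 1 for the pif4 difference and a median of -0.642 in the double mutant over genes that fell in the wild type. A pseudocount of 0.1 gave 0 for the pif4 difference, with medians of -0.733 (double mutant, fallen) and 0.665 (pif4, risen), and size factors -0.693 (double mutant, fallen). The replicate block gave 5 genes for the pif4 difference and -0.644 (double mutant, fallen). The block within temperature gave 13 and 47 genes for pif4 at 22 °C and 29 °C (7 higher and 40 lower at 29 °C), 8 for the pif4 difference, 27 for the double mutant against pif4 (21 higher and 6 lower), 2 lists for the double mutant at 29 °C and 2 genes shared by the mutants. Apart from these and the values beside the results, the blocks changed no count by over 1.5 times. The wild type and pif4 at 29 °C correlated at 0.47, 0.69 and -0.32 by number, so not every number exceeded 0.1 and they were not treated as paired, although replicates 1 and 2 did correlate. Without replicate 1 at 29 °C, counts were 0 (double mutant at 29 °C), 14 (pif4 at 29 °C), 10 (double mutant against pif4) and 0 shared, and the median was -0.731 (double mutant, fallen). Without replicate 2 at 29 °C they were 0, 13, 7 and 0, with 5 lists in the double mutant difference and medians of -0.807 (double mutant, fallen), 0.689 (pif4, risen) and -0.804 (pif4, fallen). Reversed without replicate 1 at 29 °C were photosynthesis in the double mutant at 29 °C (adjusted p = 0.689), in pif4 at 29 °C (0.00232) and in the pif4 difference (9.75e-06), jasmonate in the double mutant at 29 °C (0.031) and salicylic acid defence in the double mutant difference (0.00598). Leaving out 1 library gave 1951 to 2273, 1519 to 2060 and 1524 to 2518 genes in the 3 warm responses, 1 to 4 and 2 to 4 for the double mutant at 22 °C and 29 °C, 3 to 5 and 15 to 29 for pif4, 0 to 0 and 0 to 6 for the differences, 12 to 16 for the double mutant against pif4 and 0 to 1 shared. Medians then ran from 0.628 to 0.759 and -0.744 to -0.661 (double mutant) and from 0.565 to 0.689 and -0.75 to -0.62 (pif4). For named genes, 3568 of 3816 values kept their side of the threshold with 1 library left out, 561 of 567 with size factors, 566 without the trend and 492 with only the compared libraries, and 0 changed direction while called. Values under 1 FPKM, where depth limits most, stay in the tests for genes that reach 1 FPKM in 3 libraries.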

Other observations

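The genes in this part were chosen only after their values were seen, and no explanation is offered for them. Between replicates at 29 °C, the B-box gene BBX32 was higher in replicate 2 than in replicate 1 by a mean of 6.6 log2 over the 3 genotypes, and HSP70 by 3.51 and MBF1C, a heat-responsive coactivator gene, by 2.86. BT2, BBX14 and AT3G15450, a gene known from sugar starvation and darkness, stood lower in replicate 2, with -4.8, -3.62 and -3.85. The evening clock gene GI was at 1.65, 13.2 and 2.22 FPKM in replicates 1, 2 and 3 of the wild type at 29 °C, and at 0.502, 0.304 and 0.31 at 22 °C.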
